A study of Drosophila melanogaster with 18 samples.

How the data were processed

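The series measured gene expression in guts dissected from virgin female fruit flies (Drosophila melanogaster) of the w1118 genotype, a common laboratory strain with a deletion in the white gene, at 45 days of age. The flies had eaten either a control diet (Control, 10 libraries) or a diet supplemented with Parabacteroides distasonis, an anaerobic gut bacterium of the Bacteroidales given freeze-dried (Pd, 8 libraries). Per the labels' protocols, tissue went into RNAlater, total RNA was taken with Trizol and glycogen, and libraries were made with a stranded total RNA kit that depletes ribosomal RNA. Titles number the libraries as biological replicates. Nothing states how many guts entered 1 library or whether Control and Pd libraries were handled on the same days, so p-values measure the spread between these libraries.

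Raw read counts per gene and a normalized signal table were deposited by the authors. Per the submitters' processing notes, FastQC 0.12.1, STAR 2.7.11b, featureCounts from Subread 2.1.0 and DESeq2 were used with genome build BDGP6. The annotation release and the strand setting of the counting are not given in the sources used here. In the authors' normalized signal, each value was the raw count of the same cell divided by 1 factor per library. That table was used only to check this relation. Counts were given for 24254 features, of which 8159 had no count in any library. Feature names were matched to Ensembl release 115 of the fly annotation, 24055 by name and 199 by FlyBase identifier, and coordinates are from that annotation of BDGP6. No row was a total or an unassigned class, and 0 columns of sample values were left unmapped.

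Genes were filtered with edgeR 4.0.16 (filterByExpr on group), scaled by the trimmed mean of M values (TMM) and tested with edgeR's quasi-likelihood test (robust fit, R 4.3.3), Pd against Control with no covariate. Benjamini-Hochberg adjusted p-values under 0.05 over all genes tested were counted as calls. Log2 fold changes are Pd minus Control and carry a standard error taken from the fitted fold change and its test statistic. CPM of single genes are TMM-scaled and are given as mean ± SD over the 10 Control and 8 Pd libraries. Where a gene or ratio is given as lower or higher in a number of Pd libraries, these are compared with the Control mean. Shares are percentages of all counts of a library. A fold against a group with no count was computed from 3 counts over the whole group and is a lower bound. Where Control held 1 to 3 counts, the ratio of summed counts is given with its 95% counting interval. Intervals and floors cover counting error only, since no molecular identifiers are described.

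The design, the tests, the gene lists, the rule for naming genes and the other settings were fixed before the data were examined. The 46 lists comprised 37 topics of gut biology and 9 sets of markers of tissue that a dissection could carry along. Lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over 45 lists). Camera with an estimated correlation and fry were alternatives. Replicate numbers are those of the titles. Genes named in the text are the 15 with the largest rise and the 15 with the largest fall among calls with a mean of at least 5 CPM, up to 4 members of each list past the threshold with the smallest p, and 19 genes given whatever their result. From most lists the 2 with the smallest p are given. Library composition was compared with a 2-sided exact permutation test over all 43758 splits of the libraries, adjusted over 22 measures. The smallest p this test can give is 2.29e-05 before adjustment.

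The other settings tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no filter and a filter of 1 CPM in 8 libraries, removal of rRNA and mitochondrial-genome genes, an adjusted p of 0.1, 1 or 2 surrogate variables (sva 3.50.0), the replicate number as a block, and leaving out each library in turn. Other splits of the libraries were refitted 100 times, the real split included. To look for copies of a library, counts of replicates were compared. They differed by more than sampling noise in all 73 pairs within a group (chi-square per degree of freedom 5.57 to 97.2), so no library was counted as a copy of another in its group. Pairs across the groups were not compared in this way.

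Library totals without scaling factors were also added after the data were seen, because the TMM factors ran from 0.745 to 0.956 in Control and from 1.11 to 1.32 in Pd. Counts of calls under them are given beside a list where they differ by over 1.5 times or the median turned in sign. A germline index was added after the data were seen. It is the summed CPM of 9 germline members of the ovary marker list (osk, bcd, orb, otu, nanos, vas, swa, exu and bru1), scaled to a Pd mean of 1. It entered a weighted additive fit of CPM of all counts with limma, which estimates the Pd level at an index of 0, and a second edgeR fit as a covariate. Levels from the additive fit are therefore not TMM-scaled. For 2 lists the additive fit was also run without the index. Lists were retested on the additive fit with cameraPR at the preset correlation only, so no value with an estimated correlation exists at an index of 0.

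The steps were tested on simulated data for Pd against Control over 8193 genes. With 200 changed genes and no ovary RNA, edgeR recovered 67 of 100 changes of 2-fold and 93 of 100 of 4-fold, with 8 false calls. In simulated lists, camera called 4 of 4 raised lists and 0 of 36 unchanged ones. Those lists were random genes simulated independently of each other. They therefore cannot show how camera treats real lists, whose members can move together. With ovary RNA mixed into Pd and no gut change, edgeR called 1676 genes higher and 1113 lower, and the additive fit called 0 higher and 2 lower. The simulated ovary profile was taken from the index slopes of that additive fit and mixed in by the same measured index. The few calls of the additive fit are therefore no independent check of it. With ovary RNA and 200 changed genes, the additive fit recovered 14 of 50 4-fold rises and 32 of 50 4-fold falls, 1 of 50 2-fold rises and 13 of 50 2-fold falls, and 31.0% of its calls were false. A call that ends in the additive fit is therefore not shown to be absent from the gut.

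Because the strand setting of the counting is unknown, genes that overlap others on either strand are uncertain. 38 of the 144 genes named and tested overlap an exon of another gene, 12 on the same and 30 on the opposite strand. Members of near-identical families (lysozymes, Jonah proteases, lysosomal mannosidases, PGRP-SC1a and its copy, histones, rRNA units) are uncertain too, since reads could be split between copies.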

Results

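Gene expression was measured by total RNA sequencing in dissected guts of old virgin female flies on 2 diets. The question the labels state is which transcripts change with lifelong feeding of freeze-dried Parabacteroides distasonis, in a study of lifespan and gut barrier integrity. The files held 10 Control and 8 Pd libraries. Total counts ranged from 1410275 to 3635370 in Control and from 1274499 to 2912132 in Pd, and the group means did not differ past the threshold (adjusted exact permutation p = 0.493). Mean features detected went from 10652 ± 446 to 11213 ± 334 (SD, adjusted exact permutation p = 0.0187).

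Transcripts of the ovary were higher in every Pd gut library than in any Control library. The summed share of the ovary and eggshell marker list went from 0.0130 ± 0.00537% to 0.530 ± 0.345% of counts (SD, n = 10 and 8, adjusted exact permutation p = 5.03e-04). The lowest Pd library, Pd 3, held 0.0949% (95% Wilson interval 0.0914 to 0.0985%), and no Control library exceeded 0.0199%. This share, here and below, sums the 33 genes of that list alone. It is not the share of ovary RNA in a library, which was not measured. Fat body and yolk markers went from 0.148 ± 0.166% to 0.701 ± 0.589% (adjusted exact permutation p = 0.00503), and hemocyte markers from 0.0115 ± 0.00916% to 0.0384 ± 0.0190% (adjusted exact permutation p = 0.00141). Head and eye markers went from 0.00415 ± 8.55e-04% to 0.00869 ± 0.00232% (adjusted exact permutation p = 5.03e-04). Of the 15 genes of that list only norpA had enough counts to be tested, so the share is mostly that gene. Over the Pd libraries norpA had an r of 0.841 with the germline index. Malpighian tubule markers went the other way, from 0.347 ± 0.117% to 0.220 ± 0.0566% (adjusted exact permutation p = 0.0225). Shares of muscle, neuronal, tracheal and hindgut markers did not differ past the threshold (adjusted exact permutation p = 0.946, 0.596, 0.187 and 0.273).

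The gut's own abundant transcripts took a smaller share in Pd. Trypsin and Jonah protease genes, the main digestive endopeptidases of the midgut, went from 6.49 ± 2.11% to 2.34 ± 0.678% of counts (adjusted exact permutation p = 6.28e-04). The 10 most abundant features of each library went from 14.5 ± 1.72% to 9.93 ± 1.52% (adjusted exact permutation p = 5.03e-04). Mitochondrial rRNA went from 5.25 ± 1.66% to 3.45 ± 0.633% and the rest of the mitochondrial genome from 4.11 ± 1.06% to 2.65 ± 0.615% (adjusted exact permutation p = 0.00542 for both). The cytosolic rRNA class went from 0.0140 ± 0.0148% to 0.00144 ± 3.62e-04% (adjusted exact permutation p = 0.0205), and spliceosomal snRNA from 0.487 ± 0.121% to 0.674 ± 0.105% (adjusted exact permutation p = 0.00542). The cytosolic rRNA class was mostly the feature pre-rRNA:CR45845, which is also among the largest falls below. It did not hold the rRNA pseudogene 28SrRNA-Psi:CR40596, so it is not all the rRNA left after depletion. snoRNA, transposable element, pseudogene and protein-coding shares did not differ past the threshold (adjusted exact permutation p = 0.946, 0.189, 0.183 and 0.114).

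**Figure D1:**
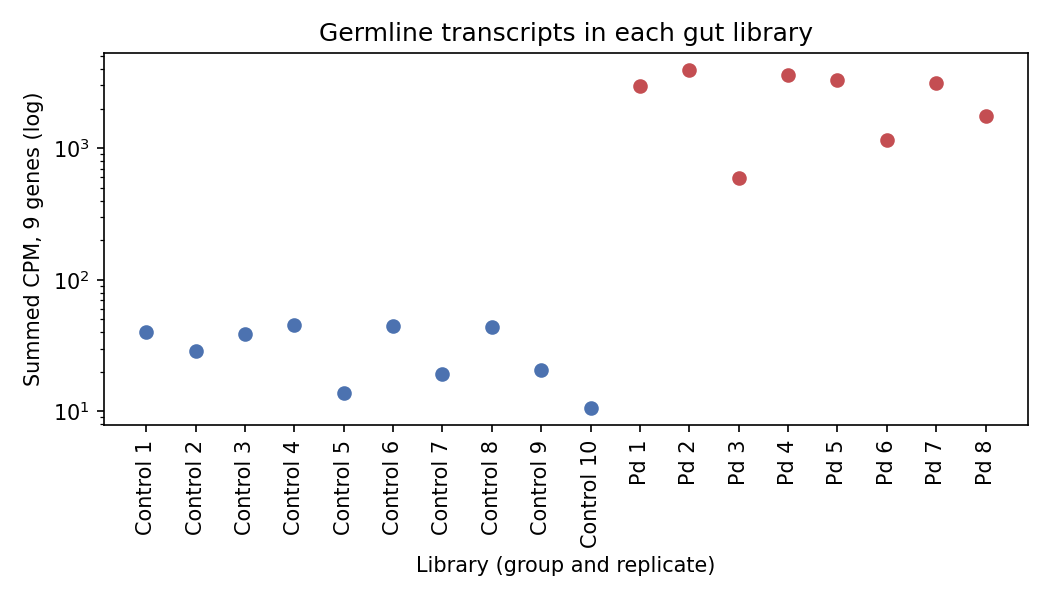
Summed CPM of 9 germline genes (y, log scale) in each library (x, group and replicate), 1 point per library, Control in blue and Pd in red. The 8 Pd libraries lie between 594 and 3937 CPM, all above the 10 Control libraries at 10.6 to 45.3 CPM.

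Most genes tested differed between the groups. Of 8193 genes, 2625 were higher and 2307 lower in Pd by edgeR, together 60.2%. The TMM factors did not overlap between the groups (0.745 to 0.956 in Control, 1.11 to 1.32 in Pd), so all changes are relative to the TMM-scaled total. With library totals in place of TMM scaling, a setting added after the data were seen, log2 changes were larger by a median of 0.55, 4451 genes were higher and 920 lower (82.9% of calls higher against 53.2%), and 44 of the 2307 lower genes were called higher. Of the genes named below, LysC, LysD, mRpL28, Ssk, Tsp2A, foxo, Pink1, His4r, Argk1, Syx1A, elav, PGRP-LE, RpS30 and Xbp1 lost the call with library totals. A change of at least 2-fold was fitted for 1321 of the higher and 1088 of the lower genes. 813 higher and 453 lower genes had no overlap between the groups, where chance gives 0.00229% of genes in each direction. The first principal component held 53.4% of the variance and separated the groups. Genes called higher started from a median of 16.6 CPM in Control and genes called lower from 108 CPM. Across the 8 Pd libraries, 94.2% of the higher genes correlated positively with the germline index, against 39.5% of the lower genes and 54.8% of the others, counted across genes, which are not independent replicates. At a germline index of 0, 15 genes were higher and 274 lower, among them 2 of the 2625 higher calls (MED7 and CG1943, named after their values were seen) and 262 of the 2307 lower calls. At an unadjusted p under 0.05 that fit called 683 genes higher and 696 lower, and edgeR with the index as a covariate called 506 and 381 by adjusted p. Without Control 3, the fit at an index of 0 gave 134 higher and 381 lower genes, and without Pd 6 it gave 5 higher and 321 lower.

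**Figure D2:**
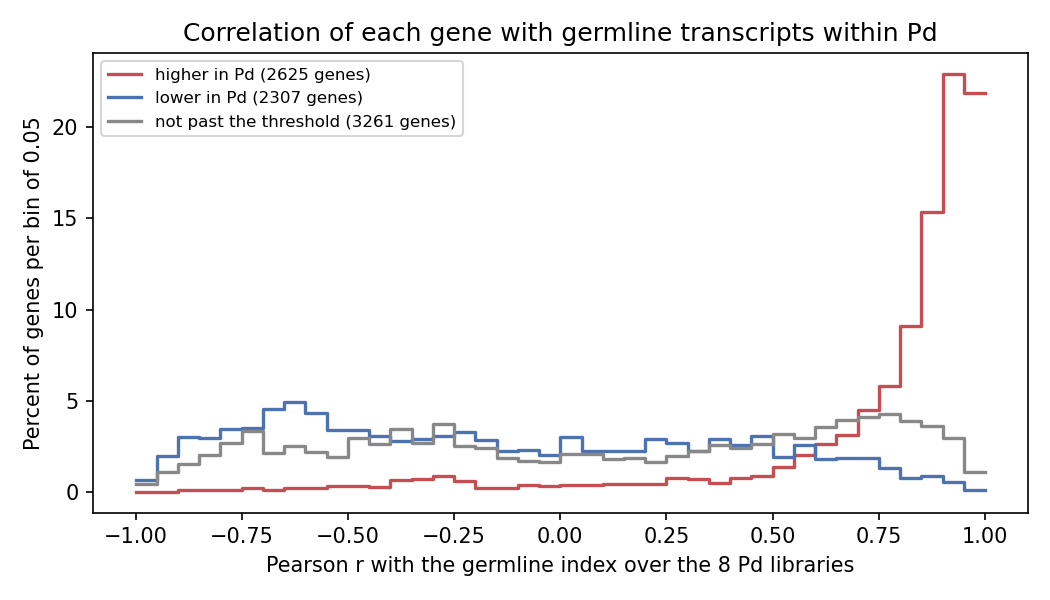
Percent of genes (y) per bin of Pearson r with the germline index over the 8 Pd libraries (x), for genes higher in Pd, lower in Pd and not past the threshold. The median r was 0.886 for higher genes, -0.215 for lower genes and 0.117 for the others, across genes.

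Genes known from the female germline and eggshell were among the largest rises. Kots (FBgn0038191; chromosome 3R, 13960712 to 13964174, minus strand), CG11674, CG4476 and CG14931 had no count in any Control library and reached 98.4 ± 48.3, 63.5 ± 33.0, 63.5 ± 38.7 and 27.9 ± 12.9 CPM in Pd, at least 722-, 480.0-, 483- and 201-fold higher. dhd, a thioredoxin of the female germline, rose from 0.794 ± 0.868 to 899 ± 456 CPM, nanos, the posterior determinant of the embryo, from 0.419 ± 0.712 to 304 ± 152 CPM, and Pxt, a cyclooxygenase-like peroxidase, from 0.281 ± 0.334 to 205.5 ± 101 CPM. With 1 to 3 Control counts in all, the count ratio was 1808 (500.4 to 14926) for Cyp6a19, a cytochrome P450, 1556 (431 to 12848) for the germline gap junction gene zpg and 1488 (267 to 58769.5) for CG6927. It was 1507 (270.5 to 59527) for the ion channel gene rpk, 831 (284 to 4031) for the eggshell gene fs(1)N and 1115 (200.1 to 44039) for CG14545. The Control counts of zpg and CG14545 came from Control 1 alone, that of CG6927 from Control 7 and that of rpk from Control 10. dec, a chorion gene, rose by 9.05 ± 1.25 (log2 ± SE, adjusted p = 7.47e-06), and by 8.11 without Pd 7. CG16826 (chromosome 2L, 13347773 to 13349020, plus strand) rose from 1.70 ± 3.23 to 2288 ± 4477 CPM (adjusted p = 4.45e-05), led by Pd 3 at 13007 CPM, and its log2 change of 10.45 was 8.86 without that library. All 15 rose with an adjusted p of at most 4.45e-05, 13 of them had an r with the germline index above 0.8, and 0 were still called at an index of 0. Since nanos is 1 of the 9 genes of the index, its own r and lost call carry no information. CG16826 had the lowest r, -0.74, so its lost call does not show that it rose with the index.

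Among the largest falls were 2 lysosomal mannosidase genes, 1 Jonah protease gene, 1 mitochondrial gene, 1 pre-rRNA feature and 1 rRNA pseudogene. LManVI (chromosome 2L, 8777661 to 8781252, minus strand), a lysosomal alpha-mannosidase gene, fell from 1075 ± 652 to 36.2 ± 28.4 CPM (log2 -4.88 ± 0.58, adjusted p = 1.45e-06, lower in 8 of 8 Pd libraries), and the related LManV had a log2 change of -4.14 ± 0.76. CG5892 fell from 37.2 ± 30.8 to 0.552 ± 0.726 CPM and had the largest fitted fall, -5.79 ± 0.90. Ugt35B1, a glycosyltransferase, changed by -4.08 ± 0.89, CG18417 and CG30043 by -4.001 ± 0.53 and -3.66 ± 0.51, CG6733 by -3.97 ± 0.79 and CG9259 by -3.96 ± 0.96. Control 3, 4 and 5 lay within or below the Pd range in Ugt35B1, CG6733 and CG9259. They held 3.29, 1.44 and 0 CPM of Ugt35B1, 3.62, 5.04 and 2.03 CPM of CG6733, and 6.26, 2.16 and 0 CPM of CG9259. The Pd libraries ran from 2.08 to 16.2, from 1.92 to 8.78 and from 4.48 to 23.2 CPM in these genes. The Jonah protease Jon65Aii fell from 2599 ± 1821 to 171 ± 237 CPM (log2 -3.92 ± 0.86), and the mitochondrial gene mt:ND4L, which overlaps mt:ND4, from 44.5 ± 29.7 to 2.15 ± 1.28 CPM (log2 -4.38 ± 0.48). The feature pre-rRNA:CR45845 and the rRNA pseudogene 28SrRNA-Psi:CR40596 changed by -4.06 ± 0.68 and -3.88 ± 0.94, CG4830 by -4.16 ± 1.13 and CG17192 by -4.03 ± 1.29. In Control, 28SrRNA-Psi:CR40596 ran from 73.9 CPM (Control 8) to 5543 CPM (Control 10), and the low end overlapped Pd, with 116 CPM in Pd 4. sens-2, a zinc finger gene, changed by -5.25 ± 1.13, and by -2.54 without Control 4, which alone held 3550.0 CPM. Adjusted p-values of the 15 ranged from 5.31e-07 to 0.0119, and 7 were still called lower at a germline index of 0. Leaving out 1 library moved 6 more of these falls by over 1.5 times: CG17192 (-3.09 without Control 2, -5.35 without Pd 8), CG9259 (-3.25 without Control 9), 28SrRNA-Psi:CR40596 (-3.01 without Control 10), and CG4830, LManV and Jon65Aii (-5.66, -5.11 and -4.85 without Pd 2).

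Germline and proliferation genes moved as groups. In the ovary and eggshell list, 14 of 15 tested members rose and 0 fell (the same counts adjusted over the list alone). osk (oskar, the organizer of germ plasm; chromosome 3R, 8935126 to 8938395, plus strand) rose from 0.289 ± 0.345 to 155 ± 74.5 CPM (log2 8.93 ± 0.51, adjusted p = 5.47e-10, higher in 8 of 8 Pd libraries), and the RNA-binding gene orb from 1.47 ± 0.905 to 254 ± 127 CPM. Camera placed the list up (adjusted p = 2.10e-10, adjusted p = 0.223 with an estimated correlation). 4 of the 15 members averaged at least 5 CPM in Control guts, and 2 were also in another list. Of the piRNA and transposon silencing list, which guards the germline genome, 20 of 23 rose and 1 fell (21 higher and 2 lower adjusted over the list alone, 21 higher and 0 lower by library totals). spn-E stood at log2 6.20 ± 0.41 and AGO3 at log2 6.29 ± 0.42 (camera adjusted p = 4.78e-09, adjusted p = 0.223 with an estimated correlation). Of the cell cycle and DNA replication list, 49 of 50 rose and 0 fell (the same counts adjusted over the list alone; median log2 3.20, or 3.75 by library totals, camera adjusted p = 2.85e-21, adjusted p = 0.223 with an estimated correlation). CycB, the mitotic cyclin B (chromosome 2R, 22803521 to 22806948, minus strand), rose from 8.00 ± 3.98 to 1258 ± 602 CPM (adjusted p = 5.47e-10) and pim, the securin gene, from 0.826 ± 0.783 to 64.0 ± 27.8 CPM. Over the 8 Pd libraries, the summed CPM of the cell cycle list had a Pearson r of 0.994 with the germline index (exact p = 7.44e-05, adjusted over 5 relations 3.72e-04), a Spearman rho of 0.976 (exact p = 3.97e-04, adjusted 9.92e-04), and an r of 0.984 without Pd 3 and Pd 6, which lay farthest from the median. The piRNA list had r 0.968 (exact p = 6.20e-04, adjusted 0.00155), rho 0.976 (exact p = 3.97e-04, adjusted 9.92e-04) and r 0.986 without those libraries. At an index of 0 no member of the piRNA list, of which vas is part of the index, or of the cell cycle list was called, and neither list was past the threshold (adjusted p = 0.970 and 0.508). The ovary list supplies the index itself, so its own value there (adjusted p = 0.691) carries no information. Histone genes were split, with 2 higher and 2 lower of 5 tested (the same counts adjusted over the list alone, 3 higher and 0 lower by library totals, where the median log2 went from -0.19 to 0.37, camera adjusted p = 0.873). His2Av stood at log2 1.53 ± 0.19 and His4r at log2 -0.60 ± 0.15.

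Digestive protease genes fell as a group, and this fall held at a germline index of 0. Of 27 tested trypsin and Jonah genes, 23 fell and 0 rose (0 higher and 24 lower adjusted over the list alone), with a median log2 change of -2.03, or -1.42 by library totals. yip7 (chromosome 3L, 6035216 to 6036175, plus strand) fell from 13392 ± 4989 to 3524 ± 937 CPM (log2 -1.93 ± 0.24, adjusted p = 2.28e-06, lower in 8 of 8 Pd libraries). etaTry, a trypsin, fell from 232 ± 66.7 to 62.1 ± 21.7 CPM (adjusted p = 3.04e-06), Jon99Fii from 3474 ± 1550.4 to 553 ± 237 CPM (adjusted p = 3.47e-06) and Jon99Cii from 3090.1 ± 2013 to 363 ± 196 CPM (adjusted p = 4.56e-06). Camera placed the list down (adjusted p = 4.36e-08, adjusted p = 0.223 with an estimated correlation). With the index, 13 members were still lower and the list stayed down (adjusted p = 3.74e-32 by the preset correlation alone). Among amylases, maltases and mannosidases, 8 fell and 3 rose of 20 (the same counts adjusted over the list alone, 3 higher and 5 lower by library totals, where the median log2 went from -0.10 to 0.39 and camera had adjusted p = 0.00508, camera adjusted p = 0.212 with TMM). Mal-A5, a maltase, stood at log2 3.00 ± 0.30 and LManI at log2 -3.602 ± 0.48. In lipid digestion and absorption, 7 fell and 2 rose of 19 (the same counts adjusted over the list alone, 3 higher and 6 lower by library totals, where the median log2 went from -0.06 to 0.41 and camera had adjusted p = 0.00324, camera adjusted p = 0.145 with TMM). The sterol-binding gene Npc2d stood at log2 -2.61 ± 0.45 and CG10116 at log2 -1.80 ± 0.34. Over the 8 Pd libraries the trypsin and Jonah list had, with the germline index, r 0.476 (exact p = 0.235, adjusted 0.294), rho 0.262 (exact p = 0.536, adjusted 0.670) and r 0.713 without Pd 3 and Pd 6. The ovary marker share was 0.0949 to 1.06% in these Pd libraries, against at most 0.0199% in Control.

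**Figure D3:**
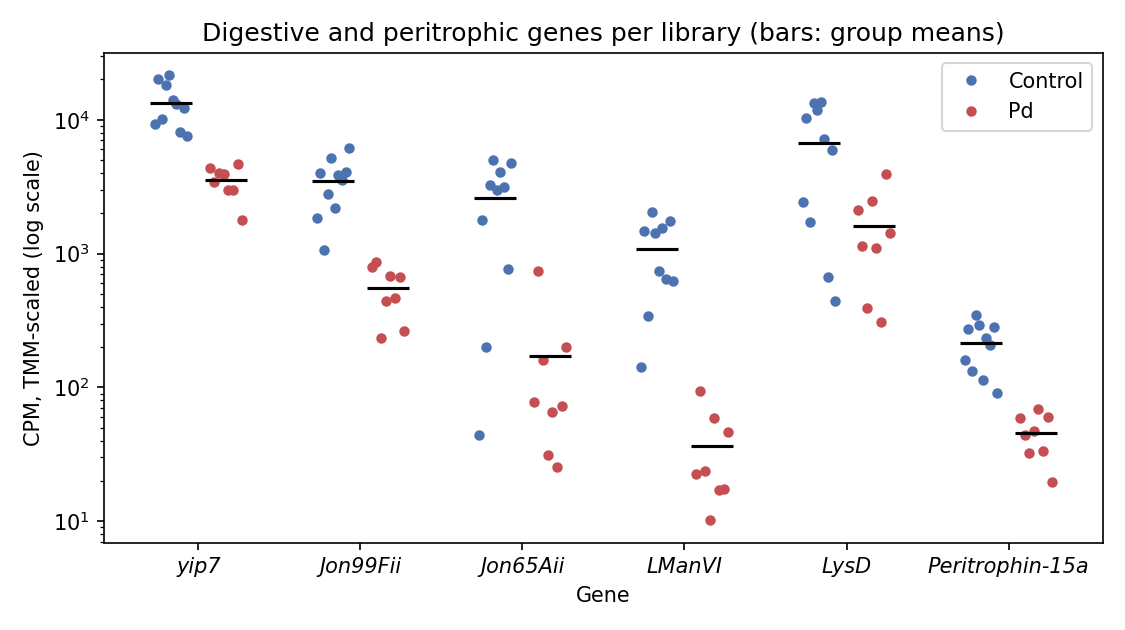
TMM-scaled CPM (y, log scale) of 6 genes of digestion and the peritrophic matrix (x), 1 point per library, Control in blue and Pd in red, with bars at the group means. yip7 averaged 13392 CPM in Control and 3524 CPM in Pd, and LManVI 1075 and 36.2 CPM.

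Genes of the peritrophic matrix, the chitinous sleeve that lines the midgut, fell too. 8 of 13 tested members were lower and 0 higher (the same counts adjusted over the list alone, 0 higher and 4 lower by library totals, camera adjusted p = 0.0187, adjusted p = 0.223 with an estimated correlation). Peritrophin-15a fell from 214 ± 86.9 to 45.6 ± 16.7 CPM (log2 -2.23 ± 0.29, adjusted p = 3.78e-06) and the chitin synthase Chs2 from 167 ± 49.5 to 48.6 ± 19.8 CPM. Crys (drosocrystallin), given whatever its result, stood at 73.9 ± 84.6 CPM in Control and 71.6 ± 63.5 CPM in Pd (log2 -0.05 ± 0.56, adjusted p = 0.944), and without Control 3 at 0.58 (adjusted p = 0.315) and by library totals at 0.40 (adjusted p = 0.553). Of 7 tested lysozymes, bacterial cell wall hydrolases, 3 fell and 0 rose (the same counts adjusted over the list alone, 1 higher and 1 lower by library totals, camera adjusted p = 0.286). LysE stood at log2 -3.28 ± 0.82, LysD at log2 -2.06 ± 0.66 and LysC at log2 -1.92 ± 0.65. At a germline index of 0 both lists were down (adjusted p = 0.00506 and 0.00506 by the preset correlation), with the lysozymes at adjusted p = 0.572 with an estimated correlation and no index. The mean ovary marker share beside them, which counts the marker genes only, was 0.530% against 0.0130%.

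Mitochondrial energy genes were mostly lower. 70 of 71 tested nuclear genes of oxidative phosphorylation were lower and 0 higher (0 higher and 71 lower adjusted over the list alone, 0 higher and 46 lower by library totals), with a median log2 change of -0.96, or -0.39 by library totals (camera adjusted p = 2.72e-20, adjusted p = 0.223 with an estimated correlation). UQCR-C1, of complex III, fell from 651 ± 101 to 287 ± 35.3 CPM (adjusted p = 1.34e-07, lower in 8 of 8 Pd libraries) and ND-75, of complex I, from 258 ± 34.0 to 112 ± 20.8 CPM. All 12 tested protein-coding genes of the mitochondrial genome fell (the same counts adjusted over the list alone, camera adjusted p = 3.35e-07, adjusted p = 0.223 with an estimated correlation). mt:ND1 stood at log2 -1.76 ± 0.17 and mt:ND5 at log2 -1.77 ± 0.19. Of glycolysis and TCA cycle genes, 25 of 35 fell and 0 rose (the same counts adjusted over the list alone, 5 higher and 14 lower by library totals, camera adjusted p = 1.18e-07, adjusted p = 0.223 with an estimated correlation). SdhD stood at log2 -1.01 ± 0.11 and mAcon1 at log2 -1.20 ± 0.14. Of fatty acid beta-oxidation genes, 21 of 27 fell and 0 rose (the same counts adjusted over the list alone, 4 higher and 10 lower by library totals, camera adjusted p = 1.20e-05, adjusted p = 0.223 with an estimated correlation). Acox3 stood at log2 -2.03 ± 0.22 and CPT2 at log2 -1.03 ± 0.10. At a germline index of 0 all 4 lists were still down (adjusted p = 1.25e-14, 1.71e-11, 0.00176 and 1.18e-07), but only 2, 5, 3 and 4 of their members were called. Oxidative phosphorylation genes had, with the germline index, r 0.246 (exact p = 0.548, adjusted 0.548), rho 0.167 (exact p = 0.703, adjusted 0.703) and r -0.360 without Pd 3 and Pd 6. The Pd libraries with these falls carried a mean ovary marker share of 0.530% against 0.0130% in Control.

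Lipid synthesis genes went both ways. 8 rose and 9 fell of 29 (7 higher and 9 lower adjusted over the list alone, 15 higher and 4 lower by library totals, where the median log2 went from -0.20 to 0.35, camera adjusted p = 0.445). The glycerolipid enzyme gene Gpat4 stood at log2 -1.52 ± 0.17, Lpin at log2 -1.37 ± 0.17 and mdy, a diacylglycerol acyltransferase, at log2 1.74 ± 0.22. Cytosolic ribosomal protein genes were lower in 69 and higher in 2 of 83 cases relative to the TMM-scaled total (2 higher and 72 lower adjusted over the list alone, 6 higher and 0 lower by library totals, where the median log2 went from -0.51 to 0.05, camera adjusted p = 3.99e-08, adjusted p = 0.572 with an estimated correlation). Their share of all counts did not differ past the threshold (9.55 ± 1.68% to 9.82 ± 1.33%, adjusted exact permutation p = 0.789). RpS5b, a paralog used in the ovary, rose from 1.10 ± 0.971 to 263 ± 146 CPM, and RpS30 changed by -0.76 ± 0.14. With the index at 0 that list was not past the threshold (adjusted p = 0.0778). Mitochondrial ribosomal protein genes (10 higher and 6 lower of 72, 3 higher and 3 lower adjusted over the list alone, 48 higher and 0 lower by library totals, where the median log2 went from -0.03 to 0.53, camera adjusted p = 0.873) were not called as a list. Nor were proteasome subunits (3 higher and 1 lower of 31, 0 higher and 0 lower adjusted over the list alone, 30 higher and 0 lower by library totals, where camera had adjusted p = 0.0342, camera adjusted p = 0.776 with TMM). mRpS10 and mRpL28 stood at log2 0.94 ± 0.18 and -0.80 ± 0.16, and Prosalpha7 and Rpt1 at log2 0.36 ± 0.10 and -0.28 ± 0.09, where Rpt1 was called higher by library totals (0.27, adjusted p = 0.0254). Ovary markers stood beside these lists at 0.530% against 0.0130% of counts.

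**Figure D4:**
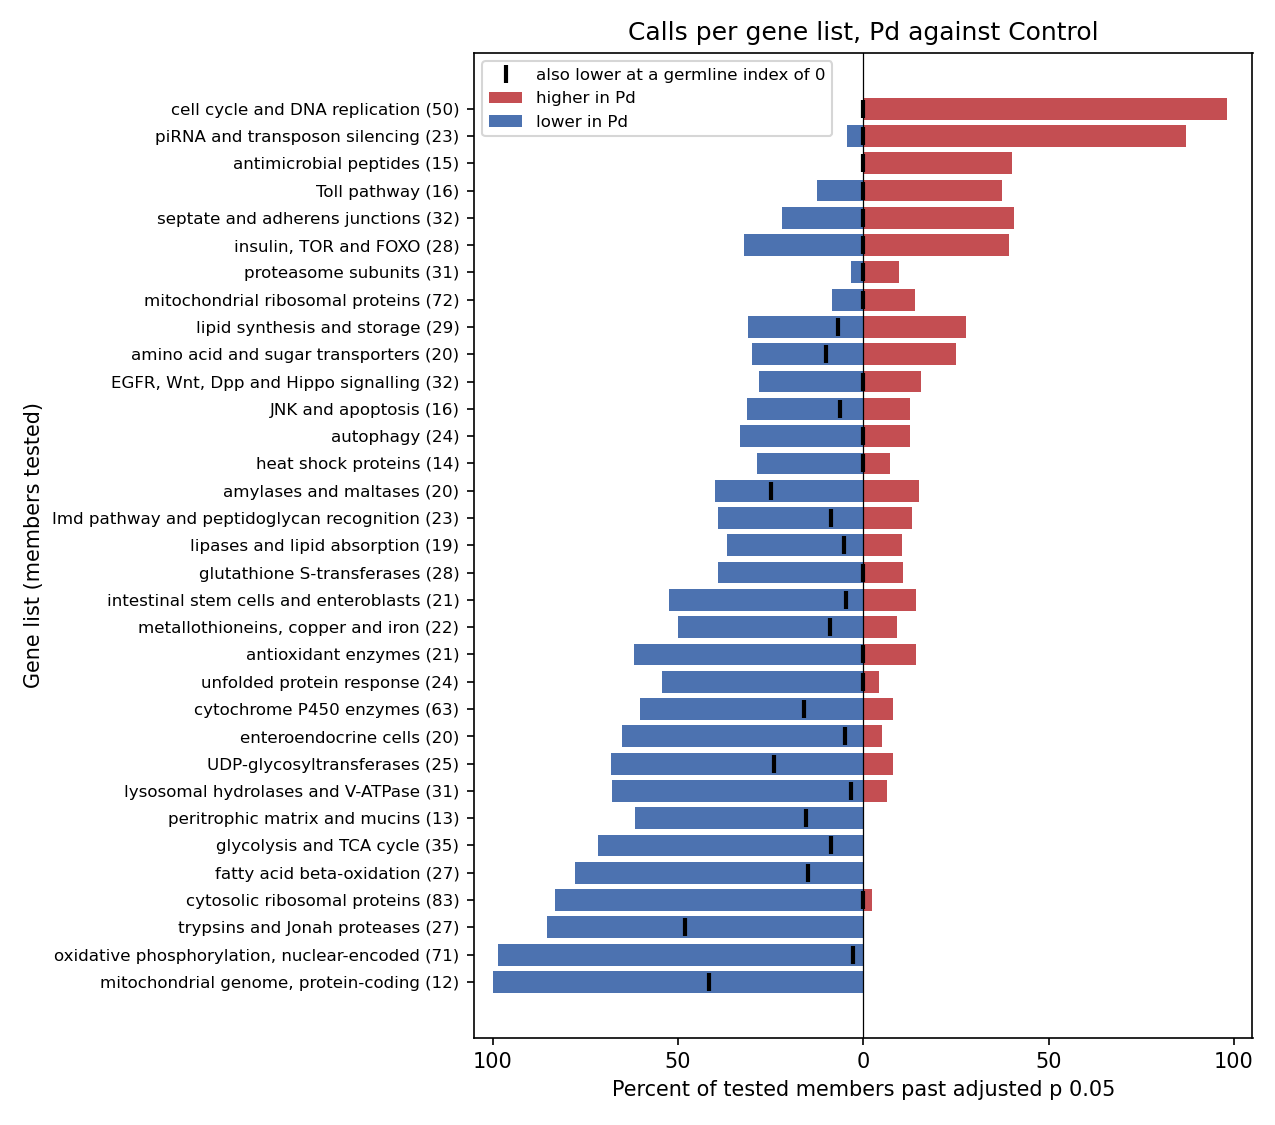
Percent of tested members called higher in Pd (red, right) or lower (blue, left), with ticks for members also lower at a germline index of 0. Rows are the gut lists with at least 12 tested members (y, members tested in brackets). The mitochondrial genome list lies at the lower end with 12 of 12 members down (11 by library totals). Oxidative phosphorylation follows with 70 of 71 down (46 by library totals), and the cell cycle list lies at the other end with 49 of 50 up.

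Detoxification genes were mostly lower. Of 63 tested cytochrome P450 genes, 38 fell and 5 rose (the same counts adjusted over the list alone, 9 higher and 28 lower by library totals, camera adjusted p = 4.86e-06, adjusted p = 0.223 with an estimated correlation). Cyp12a4 fell from 300.5 ± 90.04 to 65.1 ± 14.3 CPM (adjusted p = 3.39e-08) and Cyp6a21 from 60.1 ± 29.9 to 7.44 ± 2.66 CPM. Of 25 UDP-glycosyltransferases, 17 fell and 2 rose (2 higher and 18 lower adjusted over the list alone, camera adjusted p = 6.48e-05, adjusted p = 0.223 with an estimated correlation). Ugt49B1 stood at log2 -2.01 ± 0.20 and Ugt37A2 at log2 -2.91 ± 0.31. With the germline index both lists stayed down (adjusted p = 1.46e-04 and 5.37e-06), with 10 and 6 members called. The ovary marker share was 0.530% against 0.0130% in Control. Glutathione S-transferases went 3 up and 11 down of 28 (the same counts adjusted over the list alone, 7 higher and 4 lower by library totals, where the median log2 went from -0.21 to 0.34, camera adjusted p = 0.179). GstO3 stood at log2 -1.40 ± 0.20 and GstO1 at log2 1.19 ± 0.18. GstD1 was at 782 ± 286 CPM in Control and 772 ± 246 CPM in Pd (log2 -0.02 ± 0.22, adjusted p = 0.946).

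Antioxidant genes were down as a list by camera (adjusted p = 0.0215 with TMM, adjusted p = 0.241 with an estimated correlation), with 13 lower and 3 higher of 21 (4 higher and 14 lower adjusted over the list alone, 6 higher and 4 lower by library totals, where the median log2 went from -0.49 to 0.09 and camera had adjusted p = 0.0729). Sod1, the cytosolic superoxide dismutase, fell from 386 ± 64.6 to 204.6 ± 21.6 CPM (adjusted p = 2.93e-06, lower in 8 of 8 Pd libraries) and cnc, the Nrf2 homolog, from 558 ± 56.4 to 294 ± 69.8 CPM. Duox, an oxidase that makes reactive oxygen at epithelia, rose from 0.902 ± 1.14 to 72.3 ± 36.1 CPM (log2 6.17 ± 0.55, adjusted p = 5.35e-08). Within Pd it was lowest in Pd 3 and Pd 6 (23.1 and 29.4 CPM), where the germline index was lowest (0.232 and 0.453). Duox was not called at an index of 0. Of unfolded protein response genes, 13 fell and 1 rose of 24 (1 higher and 14 lower adjusted over the list alone, 8 higher and 1 lower by library totals, where the median log2 went from -0.48 to 0.08 and camera had adjusted p = 0.225, camera adjusted p = 0.00898 with TMM, adjusted p = 0.498 with an estimated correlation). Herp stood at log2 -1.31 ± 0.16 and sip3 at log2 -0.55 ± 0.11, or 3.46e-05 with no call by library totals. Xbp1, lower in the edgeR test (-0.62 ± 0.19), was higher at a germline index of 0 (702 to 1139.6 CPM of all counts, adjusted p = 0.0133) and is named after its values were seen. Heat shock genes were not called as a list (1 higher and 4 lower of 14, the same counts adjusted over the list alone, 6 higher and 2 lower by library totals, where the median log2 went from -0.11 to 0.45, camera adjusted p = 0.902). The heat shock factor Hsf stood at log2 0.90 ± 0.13 and the noncoding lncRNA:Hsromega at log2 -1.23 ± 0.29. Hsp22 had no count in any library. Metal homeostasis genes were down by camera (adjusted p = 0.0166, adjusted p = 0.241 with an estimated correlation) with 11 lower and 2 higher of 22 (the same counts adjusted over the list alone). The metal-responsive factor MTF-1 stood at log2 -0.94 ± 0.15 and the zinc transporter Zip42C.2 at log2 -2.53 ± 0.41. After setting the index to 0 the metal list stayed down (adjusted p = 0.0494), and the antioxidant and unfolded protein response lists were not past the threshold (adjusted p = 0.0624 and 0.814), beside an ovary marker share of 0.530% against 0.0130% in Control.

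Antimicrobial peptide genes were higher in part. 6 of 15 tested rose and 0 fell (the same counts adjusted over the list alone, 10 higher and 0 lower by library totals, where camera had adjusted p = 0.223, camera adjusted p = 0.0128 with TMM, adjusted p = 0.572 with an estimated correlation). DptA (diptericin A) rose from 4.47 ± 4.97 to 68.9 ± 75.4 CPM (log2 3.92 ± 0.73, adjusted p = 1.70e-04, above the Control mean in 8 of 8 Pd libraries) and DptB from 2.63 ± 3.63 to 19.4 ± 17.1 CPM (log2 2.79 ± 0.71, and 3.45 without Control 3). Drs (drosomycin) was at 128 ± 246 CPM in Control and 244 ± 339 CPM in Pd (log2 0.92 ± 1.20, adjusted p = 0.525), with 736 CPM in Control 3 and 1044 CPM in Pd 8. Its log2 change was 2.02 without Control 3 (adjusted p = 0.158) and 0.00644 without Pd 8 (adjusted p = 0.997). AttA, too low to test, had 28 counts in Control and 71 in Pd. Of the Imd and peptidoglycan recognition list, 9 fell and 3 rose of 23 (3 higher and 8 lower adjusted over the list alone, 8 higher and 3 lower by library totals, where the median log2 went from -0.34 to 0.18, camera adjusted p = 0.162). The amidase gene PGRP-SC2 fell from 359 ± 231 to 80.4 ± 38.8 CPM (adjusted p = 9.01e-05), PGRP-LE changed by -0.83 ± 0.17, and PGRP-SC1a changed by -3.18 ± 0.86 (adjusted p = 0.00397), or by -2.05 without Control 10. Toll pathway genes counted 6 higher and 2 lower of 16 (the same counts adjusted over the list alone, 9 higher and 0 lower by library totals, camera adjusted p = 0.365). The receptor gene Tl, also laid down in the egg, stood at log2 4.33 ± 0.43 and cact at log2 0.85 ± 0.11. In the additive fit the antimicrobial peptide list was not past the threshold (adjusted p = 0.153) and 0 of its members were called. These lost calls do not show that the rise ended, since that fit recovered 14 of 50 simulated 4-fold rises. The median r of the members with the germline index over the Pd libraries was -0.31. Fat body and hemocyte marker shares, from tissues that also make these peptides, were higher in Pd (0.701% against 0.148%, and 0.0384% against 0.0115%). The fat body share includes the yolk genes. In that list 3 of 9 tested members rose and 2 fell, Hex-C and Fatp1, and it was not called (camera adjusted p = 0.759). Its higher share therefore does not show more fat body tissue in Pd.

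JAK-STAT and JNK genes were not called as lists. In the JAK-STAT and Turandot list 3 rose and 1 fell of 8 (the same counts adjusted over the list alone, 5 higher and 0 lower by library totals, camera adjusted p = 0.445). The kinase gene hop stood at log2 0.60 ± 0.11 and the phosphatase gene Ptp61F at log2 0.55 ± 0.13. The cytokine gene upd3 was at 26.7 ± 31.5 CPM in Control and 52.6 ± 60.5 CPM in Pd (log2 0.97 ± 0.72, adjusted p = 0.253), and without Control 3 at log2 1.61 (adjusted p = 0.0577). In the JNK and apoptosis list 2 rose and 5 fell of 16 (the same counts adjusted over the list alone, 5 higher and 2 lower by library totals, where the median log2 went from -0.32 to 0.21, camera adjusted p = 0.105). egr (eiger, the fly tumour necrosis factor) fell from 38.8 ± 7.58 to 14.9 ± 1.71 CPM (log2 -1.37 ± 0.14, adjusted p = 1.73e-07, lower in 8 of 8 Pd libraries) and was still called at a germline index of 0, and bsk (the Jun kinase) changed by -0.93 ± 0.14. The ovary marker share in the same libraries was 0.530% against 0.0130% in Control.

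The smooth septate junction genes, which seal the midgut epithelium, were lower or not past the threshold. Ssk (snakeskin; chromosome 3L, 20188522 to 20189779, plus strand) went from 737 ± 139 to 385 ± 303 CPM (log2 -0.94 ± 0.36, adjusted p = 0.0326, lower in 7 of 8 Pd libraries) and Tsp2A from 353 ± 91.8 to 173 ± 130.3 CPM (log2 -1.02 ± 0.36, adjusted p = 0.0197). mesh was at 1829 ± 708 CPM in Control and 993 ± 839.6 CPM in Pd (log2 -0.88 ± 0.41, adjusted p = 0.0700). Across septate and adherens junction genes, 13 rose and 7 fell of 32 (the same counts adjusted over the list alone, 17 higher and 0 lower by library totals, camera adjusted p = 0.898). p120ctn stood at log2 1.22 ± 0.16 and Nrx-IV at log2 0.93 ± 0.13. The call of Ssk was lost without Control 3 (-0.93, adjusted p = 0.0542), Control 10 (0.0514), Pd 1 (0.0588), Pd 2 (0.0633), Pd 4 (0.0619), Pd 5 (0.0586) or Pd 7 (0.0578), and mesh passed without Pd 3 (-1.19, adjusted p = 0.0151) or Pd 6 (-1.18, 0.0162). At an index of 0 the fitted differences of Ssk, mesh and Tsp2A turned positive with no call, and by library totals Ssk was at -0.43 (adjusted p = 0.294) and Tsp2A at -0.52 (0.192). The 4 smooth septate genes had, with the index over the Pd libraries, r -0.726 (exact p = 0.0437, adjusted 0.0728), rho -0.548 (exact p = 0.171, adjusted 0.285) and r 0.460 without Pd 3 and Pd 6, so the relation rests on those 2. At an index of 0 the junction list was up by the preset correlation (adjusted p = 0.00458) with 0 members called, where without the index it had adjusted p = 0.957 with an estimated correlation, beside an ovary marker share of 0.530% against 0.0130% in Control.

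Stem cell and enteroendocrine genes were mostly lower. Of the stem cell and enteroblast list, 11 fell and 3 rose of 21 (the same counts adjusted over the list alone, 5 higher and 7 lower by library totals, camera adjusted p = 0.0480, adjusted p = 0.572 with an estimated correlation). esg (escargot, a stem and progenitor cell factor) fell from 109 ± 57.5 to 28.5 ± 22.4 CPM (log2 -1.92 ± 0.43, adjusted p = 9.16e-04, below the Control mean in 8 of 8 Pd libraries) and mira from 32.9 ± 18.3 to 3.98 ± 3.40 CPM. The groups overlapped for esg, with Pd 3 above Control 1, Control 3 and Control 9, and Pd 6 above Control 3 and Control 9. Within Pd, esg was highest in Pd 3 and Pd 6 (225 and 183 counts), where the germline index was lowest (0.232 and 0.453). At an index of 0 esg was not called. Delta, the Notch ligand of stem cells, rose from 31.5 ± 10.4 to 56.3 ± 12.3 CPM (adjusted p = 8.02e-04) and the receptor gene N (Notch) and its partner Su(H) changed by 2.52 ± 0.28 and 2.08 ± 0.24 on the log2 scale. None of these rises was called at a germline index of 0. Within Pd, N was lowest in Pd 3 and Pd 6 (64.7 and 72.9 CPM), where the index was lowest (0.232 and 0.453). Of the enteroendocrine list, 13 fell and 1 rose of 20 (the same counts adjusted over the list alone, camera adjusted p = 9.36e-05, adjusted p = 0.223 with an estimated correlation). Tk (the gut hormone tachykinin; chromosome 3R, 11994175 to 12005473, minus strand) fell from 36.8 ± 10.8 to 9.25 ± 3.79 CPM (log2 -1.97 ± 0.27, adjusted p = 7.81e-06, lower in 8 of 8 Pd libraries). Syt4 stood at log2 -1.37 ± 0.12 and the prohormone convertase gene amon at log2 -1.44 ± 0.19. With the index at 0, mira and Tk were still called, and neither list was past the threshold (adjusted p = 0.811 and 0.0634), beside an ovary marker share of 0.530% against 0.0130% in Control.

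Acidification and lysosomal genes mostly fell. 21 of 31 were lower and 2 higher (the same counts adjusted over the list alone, 7 higher and 16 lower by library totals, camera adjusted p = 2.18e-06, adjusted p = 0.223 with an estimated correlation), and the list stayed down at a germline index of 0 (adjusted p = 0.0189) with 1 member called. The proton pump subunits Vha68-2 and Vha55 fell from 2727 ± 469 to 1035 ± 207 CPM (adjusted p = 2.14e-07) and from 2672 ± 505 to 1123 ± 115.4 CPM. Autophagy genes were 8 down and 3 up of 24 (the same counts adjusted over the list alone, 11 higher and 2 lower by library totals, where the median log2 went from -0.24 to 0.30, camera adjusted p = 0.0998). Pink1 stood at log2 -0.74 ± 0.12 and Atg101 at log2 -0.95 ± 0.16. Insulin, TOR and FOXO genes split 11 up and 9 down of 28 (the same counts adjusted over the list alone, 14 higher and 3 lower by library totals, camera adjusted p = 0.823). srl (the PGC-1 homolog) stood at log2 2.31 ± 0.23, alc at log2 -1.26 ± 0.18 and foxo at log2 -0.71 ± 0.18 (adjusted p = 0.00280). Thor (4E-BP) was at 334 ± 89.3 CPM in Control and 227 ± 181 CPM in Pd (log2 -0.56 ± 0.37, adjusted p = 0.196), and passed without Pd 6 (-0.85, adjusted p = 0.0398). Signalling genes of the EGFR, Wnt, Dpp and Hippo list were 5 up and 9 down of 32 (5 higher and 8 lower adjusted over the list alone, 13 higher and 3 lower by library totals, where the median log2 went from -0.25 to 0.28, camera adjusted p = 0.169). fz stood at log2 1.86 ± 0.27 and the receptor gene put at log2 0.79 ± 0.13. Amino acid and sugar transporters were 5 up and 6 down of 20 (the same counts adjusted over the list alone, 7 higher and 4 lower by library totals, where the median log2 went from -0.21 to 0.29, camera adjusted p = 0.442). The peptide transporter yin stood at log2 4.64 ± 0.44 and path at log2 1.12 ± 0.14. Clock genes were 2 up and 4 down of 11 (the same counts adjusted over the list alone, 4 higher and 3 lower by library totals, where the median log2 went from -0.40 to 0.14, camera adjusted p = 0.209). dco stood at log2 0.99 ± 0.12 and cry at log2 -1.56 ± 0.21. The mean ovary marker share was 0.530% against 0.0130% in Control.

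Marker lists of other tissues did not all move one way. Malpighian tubule markers were 12 lower and 1 higher of 25 (the same counts adjusted over the list alone, 2 higher and 8 lower by library totals, camera adjusted p = 0.00867, adjusted p = 0.506 with an estimated correlation). hth stood at log2 -1.69 ± 0.25 and ClC-a at log2 -2.10 ± 0.33, neither of them called at a germline index of 0. The list stayed down there (adjusted p = 0.00233), with 3 members called lower and 1 higher. Striated muscle markers were lower in 9 and higher in 0 of 22 (0 higher and 7 lower adjusted over the list alone, 0 higher and 1 lower by library totals, camera adjusted p = 8.16e-04, adjusted p = 0.572 with an estimated correlation). Argk1 stood at log2 -0.79 ± 0.12 and TpnC47D at log2 -1.603 ± 0.30. Hemocyte markers were higher in 6 and lower in 0 of 9 (the same counts adjusted over the list alone, camera adjusted p = 0.0540). srp stood at log2 2.14 ± 0.44 and Col4a1, a basement membrane collagen, at log2 2.26 ± 0.47. Fat body and yolk markers were 3 higher and 2 lower of 9 (4 higher and 2 lower adjusted over the list alone, 5 higher and 2 lower by library totals, camera adjusted p = 0.759). Hex-C stood at log2 -2.61 ± 0.45, Fatp1 at log2 -1.15 ± 0.26, the yolk gene Yp2 at log2 2.33 ± 0.81 (3.52 without Control 3) and apolpp at log2 1.604 ± 0.56 (adjusted p = 0.0201; 1.08 and 0.0797 without Pd 8). Neuronal markers were 2 lower and 0 higher of 5 (the same counts adjusted over the list alone, 1 higher and 0 lower by library totals, camera adjusted p = 0.234). Tracheal markers were 1 higher and 0 lower of 9 (the same counts adjusted over the list alone, 1 higher and 0 lower by library totals, where the median log2 went from -0.12 to 0.41, camera adjusted p = 0.729). Hindgut and crop markers were 3 higher and 3 lower of 11 (the same counts adjusted over the list alone, 5 higher and 2 lower by library totals, where the median log2 went from -0.11 to 0.44, camera adjusted p = 0.788). Syx1A and elav stood at log2 -0.59 ± 0.16 and -0.75 ± 0.24, sn, also used in the ovary, at log2 3.601 ± 0.38, and Tsp66E and lin at log2 5.45 ± 0.50 and 0.88 ± 0.12. The 1 tested head and eye marker, norpA, was higher (0.47 ± 0.15, adjusted p = 0.0112; 1 higher adjusted over the list alone), and its call was lost without Control 2, Control 3 or Control 7 (adjusted p = 0.0595, 0.0575 and 0.0530). The white gene w, deleted in part in w1118, had 0 counts in Control and 8 counts in 5 of the 8 Pd libraries, at most 2 in 1 library.

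In all, camera placed 21 of 45 lists past the threshold, 4 up and 17 down. With an estimated correlation 0 lists held, 9 had an unadjusted p under the threshold, and the smallest adjusted p was 0.223. fry, which does not compare a list with other genes, called 33. With library totals 21 lists passed, 18 of them as with TMM, and the median of 18 of the 45 lists turned from negative to positive, among them the antioxidant, unfolded protein response and cytosolic ribosomal lists. After setting the index to 0, 17 lists passed, 11 of them among the 21 and all 11 down. The 6 others were the Toll pathway, autophagy, signalling and tracheal lists and the junction list, all up, and the lysozymes, down (adjusted p = 0.00792, 0.00647, 0.0183, 0.0228, 0.00458 and 0.00506). Of their members 0, 0, 2, 0, 0 and 3 were called in that direction. With an estimated correlation and no index these 6 lists had adjusted p = 0.673, 0.572, 0.572, 0.938, 0.957 and 0.572. Median and mean log2 changes differed in sign for lipid synthesis (-0.20 and 0.21), histones (-0.19 and 0.24), tracheal (-0.12 and 0.30) and hindgut markers (-0.11 and 0.21) and mitochondrial ribosomal proteins (-0.03 and 0.00378), whose test pointed down, as it did for insulin signalling with a median of 0.02. None of these 6 passed. Of the marker lists, 9 of 9 fat body, 24 of 25 Malpighian, 22 of 22 muscle, 7 of 9 hemocyte, 4 of 5 neuronal, 8 of 9 tracheal and 10 of 11 hindgut members averaged at least 5 CPM in Control, and 4, 3, 0, 1, 0, 2 and 2 of them were also in another list.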

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

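The tests with the germline index and of the ratios to junction genes were chosen only after the result was seen. The splits of the libraries were planned.

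Germline genes were high in all 8 Pd libraries, and ovary tissue left on some dissected guts is a candidate source. Over the Pd libraries, the 22 tested piRNA genes that are not in the index had a median r of 0.961 with it, which is in line with 1 source in varying amount. A diet effect on the ovary, or on how often ovary stays attached, cannot be told apart from a difference in dissection, because all 8 Pd libraries lay above every Control library and the labels give no dissection batch. A biological effect of the diet on gut transcripts with the same course stays untested.

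Genes higher in Pd numbered 2625, and chance in how libraries are grouped is excluded, since 1 of 100 splits, the real one, gave as many, and the highest other split gave 490. For the 2307 lower genes it was 1 of 100, with 1380 in the highest other split, which was close to the mirror of the real one. For the 21 lists chance could not be excluded, since 27 of 100 splits gave as many and the highest other gave 28. Ovary RNA may account for most of the higher calls, but the fits with the index cannot show it. Of these calls 0.0762% (2 of 2625) were still higher at a germline index of 0 in the additive fit (0 without Pd 6, 30 without Control 3). With the index as edgeR covariate 421 were. The additive fit recovered 1 of 50 simulated 2-fold rises, so calls lost in it do not speak for ovary RNA. Ovary RNA and a diet effect on gut genes cannot be told apart here, because the index was high in Pd alone and the additive fit recovered 28% of simulated 4-fold rises.

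Trypsin and Jonah protease genes and oxidative phosphorylation genes were lower in Pd, and dilution of gut RNA by ovary RNA, or fewer enterocytes, could lower both. For the proteases, ovary dilution as the whole cause is argued against, since 56.5% of the lower calls (13 of 23, and 13 to 16 on leaving out 1 library) were still lower at a germline index of 0, where the median Pd level, in CPM of all counts with no TMM factor, was 16.1% of Control against 37.1% without the index, and the summed level 25.9% with an SE of 23.7 (12.7 to 32.1% on leaving out 1 library). For oxidative phosphorylation the median level was 75.8% without the index and 76.6% at 0, with the list down (adjusted p = 1.25e-14 by the preset correlation). The additive fit without the index called 46 members lower, so some of the 70 edgeR calls ended before the index entered. The 2.86% of calls kept at 0 (2 of 70, and 0 to 7) do not speak for dilution, since the median error also grew from 8.47 to 14.4% of Control. Dilution stays open there because the summed level at 0 was 72.5% of Control with an SE of 13.0 (69.2 to 82.0% on leaving out 1 library), a fall not clearly beyond its error. Relative to the smooth septate junction genes, proteases differed by -0.81 (log2, SE 0.4661, exact permutation p = 0.0915, adjusted over 2 ratios 0.183, lower in 6 of 8 Pd libraries) and oxidative phosphorylation genes by 0.28 (SE 0.446, exact permutation p = 0.509, adjusted 0.509, lower in 2 of 8), and with neither past the threshold a lower enterocyte share and a diet effect within enterocytes cannot be told apart.

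Single libraries stood apart from the rest of their group in 34 of 330 groups tested (10.3%), where chance gives about 1 in 20. Pd 8 did so 10 times and Control 3 9 times. In Pd 8, fat body and yolk markers held 2.01% (95% Wilson interval 2.00 to 2.03%), striated muscle markers 1.43% (95% Wilson interval 1.42 to 1.45%), hemocyte markers 0.0816% (95% Wilson interval 0.0780 to 0.0853%), tracheal markers 0.143% (95% Wilson interval 0.139 to 0.148%) and hindgut and crop markers 0.122% (95% Wilson interval 0.117 to 0.126%), against medians of 0.499, 0.493, 0.0340, 0.0270 and 0.0659% in the other Pd libraries. Pd 8 was lowest in etaTry, Gpat4 and Tk (19.5, 75.5 and 2.02 CPM, medians of the others 64.9, 135 and 10.9) and highest in cry and His4r (84.5 and 368 CPM, medians 32.0 and 194).

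In Control 3, fat body and yolk markers held 0.563% (95% Wilson interval 0.555 to 0.571%), hemocyte markers 0.0351% (95% Wilson interval 0.0331 to 0.0372%) and tracheal markers 0.0549% (95% Wilson interval 0.0524 to 0.0575%), against medians of 0.0815, 0.00759 and 0.0226% in the other Control libraries. Control 3 was highest in mesh, Crys and lin (3710.0, 312 and 54.0 CPM, medians of the others 1641, 48.6 and 38.0) and lowest in CG30043, egr and alc (12.5, 21.7 and 78.4 CPM, medians 303, 37.9 and 181).

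Control 4 was highest in sens-2, Syx1A and norpA (3550.0, 211 and 73.5 CPM, medians of the others 57.6, 110.3 and 45.0) and lowest in mRpS10 (6.48 CPM, median 17.0). Its neuronal markers held 0.0262% (95% Wilson interval 0.0239 to 0.0288%) and its head and eye markers 0.00618% (95% Wilson interval 0.00510 to 0.00748%), with medians of 0.0136 and 0.00390% in the others. Cytosolic rRNA was highest in Control 1 at 0.0492% (95% Wilson interval 0.0465 to 0.0521%), with a median of 0.0106% in the others, and snoRNA in Control 10 at 2.56% (95% Wilson interval 2.54 to 2.59%), with a median of 0.699%. Control 10 was also lowest in Hsf (37.1 CPM, median 59.8), Control 9 highest in Argk1 (1563 CPM, median 1121) and Pd 2 highest in CG18417 (14.9 CPM, median 4.16). Single Control libraries alone held counts of zpg and CG14545 (Control 1, 0.926 and 0.463 CPM), CG6927 (Control 7, 0.3315 CPM) and rpk (Control 10, 0.8845 CPM).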

How the results depend on the processing

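The germline index fits and library totals without scaling factors were chosen only after the result was seen, and the other settings were fixed in advance. Over the scalings, tools, filters and surrogate variables, 2595 to 3194 genes were higher and 1877 to 2823 lower, and 19 to 24 lists passed camera with its preset correlation. Upper-quartile scaling moved the median log2 change of all genes from 0.01 to 0.14. No gene called higher was called lower, or the other way, under any setting fixed in advance. Of 144 genes named, 112 kept their direction and side of the threshold under every setting fixed in advance. Leaving out 1 library at a time gave 2245 to 2714 higher genes, 2134 to 2477 lower genes and 20 to 23 lists. 0 lists passed with an estimated correlation and 33 with fry.

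With the replicate number of the titles as a block, 2207 genes were higher and 2496 lower, and 22 lists passed. With the number in the column names as a block, over fewer libraries, 1456 were higher and 1082 lower, and 19 lists passed. Same-numbered libraries correlated above 0.1 in 2 of 8 pairs by title and 1 of 5 by column, and 2 and 1 correlated best with their own number, so the numbers were not read as a pairing.

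At a germline index of 0 the additive fit called 15 genes higher and 274 lower, and edgeR with the index as covariate called 506 and 381. The 2 fits kept 2 and 421 of the 2625 higher calls and 262 and 359 of the 2307 lower ones. The additive fit kept 0 of the higher calls without Pd 6, 1 without Pd 2 or Pd 3, 4 without Control 8, Pd 4 or Pd 7, 7 without Pd 8 and 30 without Control 3. Of the 144 genes named, 35 kept their direction and side of the threshold in the additive fit, 81 lost the call and 28 turned in sign, against 74, 60 and 10 with the covariate. The cause was not tested.

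With library totals 4451 genes were higher and 920 lower, since the TMM factors of the groups do not overlap, and 44 genes called lower were called higher. 21 lists passed. Of the genes named, 126 kept their direction and side of the threshold, 14 lost the call and 4 turned in sign, Rpt1 to 0.27 with a call and sip3 to 3.46e-05, GstD1 and Crys without one.

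GstD1, which did not pass at -0.02, turned in sign to 0.10 with upper-quartile scaling, 0.0676 with limma-voom, 0.00214 with the filter of 1 CPM in 8 libraries, 0.24 with the column-number block and 0.49 with library totals, and ranged from -0.16 to 0.0782 on leaving out 1 library. Crys, which did not pass at -0.05, turned in sign to 0.0654 with upper-quartile scaling, 0.00952 with limma-voom, 0.0231 with 1 surrogate variable, 0.0676 with 2 surrogate variables, 0.41 with the column-number block and 0.40 with library totals, and ranged from -0.43 to 0.58 on leaving out 1 library. In the additive fit, differences in CPM turned negative for Kots (-3.51), CG11674 (-4.06), CG4476 (-7.26), Cyp6a19 (-13.3), dhd (-61.3), zpg (-9.91), Pxt (-5.83), CG6927 (-2.27), rpk (-2.47), CG14931 (-0.849), dec (-53.9), osk (-4.06), orb (-11.7), CycB (-19.8), RpS5b (-0.583), fz (-5.02) and sn (-0.743). They turned positive for mRpL28 (1.08), GstD1 (508), Ssk (240.1), mesh (782), Tsp2A (88.5), Crys (134), Thor (275), foxo (0.984), elav (3.12), Fatp1 (2.72) and Xbp1 (437), of which only Xbp1 was called. Among the negative differences, osk and orb are part of the index, so their values there carry no information. With the index as edgeR covariate, log2 changes turned for Prosalpha7 (-0.00268), GstD1 (0.48), Ssk (0.33), mesh (0.54), Tsp2A (0.24), Crys (1.51), Thor (1.13), elav (0.0355), norpA (-0.15) and Xbp1 (0.45), with no call.

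Depth limits low genes: 3 counts correspond to 0.8252 CPM in the deepest library and 2.35 CPM in the shallowest.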

Other observations

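The values here are of single libraries, and differences between single libraries were not tested. Socs36E, LysX, Uro and Yp1 were chosen after their values were seen, and upd3 and CG16826 fall under the rule for naming genes. Socs36E, a target gene of JAK-STAT signalling, was highest in Control 3 (715 CPM), Pd 3 (681 CPM) and Pd 6 (552 CPM), where upd3 stood at 109.64, 172 and 120.1 CPM. The lysozyme LysX was highest in Pd 6 and Pd 3 (630.5 and 371 CPM), followed by Control 3 at 227 CPM.

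Uro, the urate oxidase of the Malpighian tubule, was at 8.89, 0.720 and 0.406 CPM in Control 3, 4 and 5 and at 5.23, 2.56 and 22.9 CPM in Pd 2, 3 and 8, against 240.4 CPM or more in the others. Yp1, a yolk protein gene, reached 8278 CPM in Pd 8 and 2150.0 CPM in Control 3. CG16826 was high in Pd 3, Pd 6 and Pd 7 (13007, 2872 and 2179 CPM) and at or under 127 CPM in the other Pd libraries.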
